A study of Mus musculus with 4 samples.

How the data were processed

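The series compares mouse embryonic stem cells of 2 genotypes, WT and Suz12KO, on 2 Affymetrix arrays each, grouped by the sample titles. Per the labels' protocols, total RNA was extracted from 3 clones per genotype, equal amounts were pooled, and biotin-labelled targets were made by the supplier's method. Hybridisation and scanning followed the manufacturer's method, per the series' design text. The deposited values are probe set signal, an intensity on a linear scale, for 45101 probe sets. The summarisation software and its version are not given in the sources used here. In every array the mean signal without the lowest and highest 2% of values was 500.003, which shows that the deposited intensity had been scaled to 1 trimmed mean per array. Medians differed between arrays by less than the limit set beforehand for further normalization, so none was applied. Such scaling fixes the mean of each array, so a change shared by most genes cannot be measured.

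Gene symbols came from the platform annotation: 34958 probe sets had 1 symbol, 932 had several and 9211 had none here, and 64 were controls. Of those with 1 symbol, 34754 matched a gene of the GRCm38.p6 annotation, which gave the chromosome, and 0 symbols changed through the gene ID. Probe sets with several symbols or none were left out, as were controls. Values were transformed as log2(signal + 16), so fold changes of dim genes are understated. The probe set with the highest mean represented each of 18193 genes, and genes under the 30th percentile of mean level were left out, which left 12735. Suz12KO was compared with WT by limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend, two-sided, Benjamini-Hochberg adjustment over all tested genes, calls at an adjusted p under 0.05, prior degrees of freedom 7.16). Gene lists, 22 in all, were tested with camera at a preset correlation of 0.01, adjusted over the lists. Its trend option, which the fixed design had left open, was turned on after its default output had been seen, and with or without it 7 lists passed. With the correlation estimated from the data 0 lists passed. That option also tests on the residual degrees of freedom of 4 arrays, so losing a pass under it need not reflect correlation between genes. Signal within background was judged by 27 probe sets for bacterial spikes, taken as unused because they read low in every array. Where both arrays of a genotype lay at or under the highest of these, the change was given as at least N-fold, from the mean log2 signal of the brighter genotype against that highest spike value per array. This bound and the Fisher's exact test on X-linked genes were added after seeing the data. Chromosome medians were set against 10000 random gene sets of the same size, and list medians against 10000 random lists matched on mean signal in 20 bins. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

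The test, the lists, the alternatives and the following rule for named genes were fixed before the data were examined: all measured PRC2 subunits and cofactors, the 12 largest rises and 12 largest falls among calls with non-overlapping arrays, per list the 3 largest rises and 3 largest falls past the test (or the 2 brightest members where none passed), and Pou5f1, Nanog, Sox2, Gata4, Gata6, Xist and Cdkn2a. Clone and predicted gene names were not used, which concerned 14 genes called higher and 6 called lower. The procedure was tested on simulated data with 12735 genes and 200 changed ones for the comparison of Suz12KO with WT. It recovered 34% of 2-fold and 69% of 4-fold changes, and 9 of 112 calls (8.04%) were false. The simulated variances were drawn from the fitted trend model with independent noise, so these shares hold only if that model does. Alternatives were another pseudocount (1 or 64), quantile normalization, centring on the array median, no filter or a filter at the 50th percentile, the mean of a gene's probe sets, probe sets without an s, x or a suffix, all probe sets, eBayes without trend or with robust estimation, replicate number as a block, leaving out each array, and an estimated correlation in camera.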

Results

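Messenger RNA levels were measured on 4 Affymetrix expression arrays in mouse embryonic stem cells, the pluripotent cells derived from the early embryo. There were 2 arrays for wild-type cells (WT) and 2 for cells lacking Suz12 (Suz12KO). Suz12 is a core subunit of Polycomb repressive complex 2 (PRC2), which methylates lysine 27 of histone H3 and is associated with silent developmental genes. According to the labels, RNA of 3 clones per genotype was extracted separately and mixed in equal amounts. The labels do not say whether the 2 arrays of a genotype hold separate RNA, so every limma p-value below measures spread between arrays only, which may be technical. The camera and Fisher's exact tests set genes against other genes, and neither measures spread between clones or cultures. Each array gave a signal for 45101 probe sets, and the number of arrays limits the precision. The median signal was 175 and 171 in the WT arrays and 202 and 191 in the Suz12KO arrays. Probe sets for bacterial spike RNA, which read low in every array and were taken as unused, reached 141 and 191 in WT and 195 and 174 in Suz12KO, which marks the signal that background alone can give. Log2 values of the tested genes correlated at 0.948 between the WT arrays, at 0.934 between the Suz12KO arrays and at 0.905 to 0.914 between genotypes, across genes, which are not independent replicates. The ratio of 3' to 5' signal, a measure of RNA integrity, was 0.807 and 0.756 in WT and 0.889 and 0.871 in Suz12KO for Gapdh. It was 1.15 and 1.16 against 1.14 and 1.14 for Actb, and 2.55 and 2.47 against 2.43 and 2.84 for Tfrc.

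The design holds a single comparison, which asks how transcript levels of embryonic stem cells without Suz12 differ from those of wild-type cells. Suz12 itself fell. Its signal was 1095 ± 1.83 in WT and 293 ± 107 in Suz12KO (mean ± SD, n = 2 arrays each), a log2 fold change of -1.89 (SE 0.27, limma with Benjamini-Hochberg adjusted p = 0.0021). A second Suz12 probe set had a log2 fold change of -1.83, and another read 895 and 816 in WT and 25.6 and 243 in Suz12KO. The remaining ones lay within the range of the unused spikes in both Suz12KO arrays. Of these, only the one at 150 and 283 in WT was above that range in the WT arrays. The others read 55.8 and 56.1, and 47.1 and 166, in WT and cannot show a fall. Whether these probe sets lie in the deleted part of the gene is not given in the sources used here. The Suz12 call was lost when all of its probe sets were averaged (-1.67, adjusted p = 0.060).

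Among the 11 PRC2 subunits and cofactors, all of which were measured, Jarid2, Mtf2, Aebp2 and Eed rose, and Suz12 was the member that fell. Jarid2, a cofactor that helps recruit PRC2, rose by 0.95 on the log2 scale (SE 0.07), from a signal of 4610 ± 115 to 8906 ± 159 (mean ± SD, n = 2). Mtf2, a Polycomb-like cofactor, rose by 0.76 (SE 0.08), Eed, the core subunit that binds methylated histone H3, by 0.36 (SE 0.08) and Aebp2 by 0.45 (SE 0.12). The methyltransferase Ezh2 had a log2 fold change of 0.19 (limma adjusted p = 0.231) and its paralog Ezh1 one of 0.70 (adjusted p = 0.227), and neither passed the test. The Ezh1 log2 fold change was 0.061 with the mean of its probe sets, -1.07 among probe sets without an s, x or a suffix and 0.38 without WT replicate 2. The Ezh1 probe sets without such a suffix lay under the highest unused spike of any array (195). Another Ezh1 probe set with such a suffix lay above that level and changed by 0.71 (228 and 266 in WT, 362 and 471 in Suz12KO). Phf19 (0.40), Rbbp4 (-0.11), Rbbp7 (-0.09) and Phf1 (-0.27) did not pass either, but Rbbp4 did after centring (-0.28, adjusted p = 0.0461). The Phf19 log2 fold change was 0.72 without WT replicate 1 and 0.09 without WT replicate 2. The Rbbp7 log2 fold change was -0.04 without Suz12KO replicate 1 and -0.14 without Suz12KO replicate 2. The Phf1 log2 fold change was 0.05 and -0.59 without the same arrays. The Ezh2 log2 fold change was 0.12 without Suz12KO replicate 2. The counts were the same when adjusted over the list alone (4 rose, 1 fell), and the list as a whole did not pass the set test (median 0.36, camera adjusted p = 0.093, and adjusted p = 0.649 with an estimated correlation). That test includes Suz12, the targeted gene, so it does not measure the other members alone (list mean 0.13). The list median lay at percentile 99.81 among random lists of matched signal, a description across genes. Without WT replicate 1 or Suz12KO replicate 1 the median log2 fold change of PRC2 subunits and cofactors (0.32 and 0.41) did pass (camera adjusted p 0.0434 and 0.0452). Aebp2 lost its call without any 1 of the 4 arrays (adjusted p 0.0887 to 0.219), and Eed lost it without WT replicate 1 or Suz12KO replicate 2 (adjusted p 0.0991 and 0.0790). Averaging the probe sets of each gene turned the list median to -0.12 and Eed to -0.42 and ended the call of Aebp2 (0.18), and centring each array on its median ended both calls (0.19 and 0.28), and that of Aebp2 was also lost without a filter on dim genes or without such suffixes (adjusted p 0.0570 and 0.0502). The second Eed probe set read 170 and 126 in WT and 23.2 and 113 in Suz12KO, under the highest unused spike of any array (195).

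Of 12735 genes tested, 570 were higher and 700 lower in Suz12KO, and 173 of the former and 217 of the latter changed at least 2-fold. The largest rise was that of Hprt, an X-linked purine salvage enzyme, from 202 ± 86.3 in WT to 6870 ± 176 in Suz12KO (mean ± SD, n = 2), a log2 fold change of 5.04 (SE 0.23). Calcoco2, an autophagy receptor, rose by 3.84, the X-linked homeobox gene Rhox5 by 3.19, Tcl1 by 2.80, the T-box factor Tbx3 by 2.65 and Pnma5 by 2.39. Galnt6, Aire, Liph, Oas1a, Stag3 and Fcna also rose, but their WT signals lay within the range of the unused spikes. Set against that range, Galnt6 was at least 3.36-fold, Aire at least 3.45-fold, Liph at least 2.90-fold, Oas1a at least 4.86-fold, Stag3 at least 2.94-fold and Fcna at least 2.02-fold higher.

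The largest falls with signal above the unused spikes in at least 1 array of each genotype were those of Malat1, a nuclear noncoding RNA (-3.06), the skeletal muscle actin Acta1 (-2.72), the oxygen sensor Egln1 (-2.64), the cytokine Ltb (-2.63) and the peptide-processing enzyme Cpe (-2.63). The Suz12KO signals of Stmn4, Serpinb9, Ror2, Nog, Mroh2a, Trp53inp2 and Lrfn4 lay within the range of the unused spikes. Measured against that range, Stmn4 was at least 3.13-fold, Serpinb9 at least 2.54-fold, the Wnt receptor Ror2 at least 2.29-fold, the BMP antagonist Nog at least 2.03-fold, Mroh2a at least 2.58-fold, Trp53inp2 at least 2.99-fold and Lrfn4 at least 2.22-fold lower. Other probe sets of Malat1 changed by -0.06 to -2.86, and the mean over all of its probe sets (-1.20) did not pass, nor did the one used among those without an s, x or a suffix (-0.64). Averaging probe sets also ended the calls of Egln1 (-1.90), Cpe (-0.79), Trp53inp2 (-1.44), Liph (2.04), Tbx3 (1.98), Nog, Ltb and Lrfn4, and testing without a filter on dim genes ended those of Fcna, Nog and Lrfn4 (adjusted p 0.0614 to 0.0877). With a pseudocount of 1 Lrfn4 had an adjusted p of 0.0599.

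**Figure D1:**
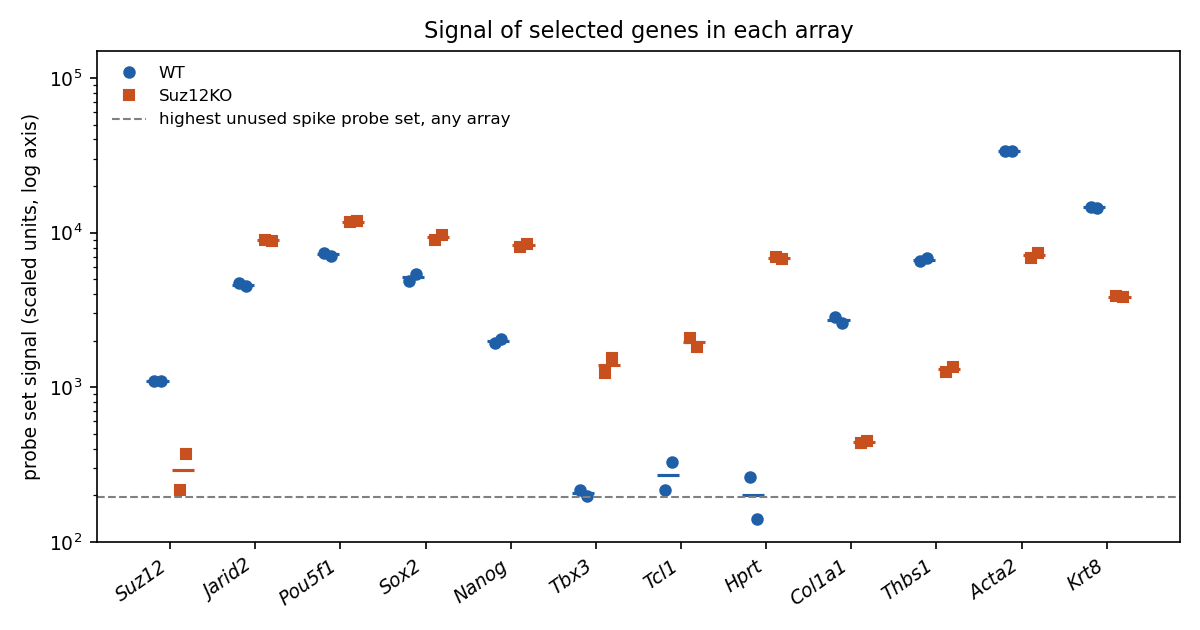
Probe set signal in scaled units (log axis) of 12 genes in each of the 4 arrays, with WT as circles, Suz12KO as squares, the mean of each genotype as a short bar and the highest unused spike probe set of any array (195) as a dashed line. Suz12, Col1a1, Thbs1, Acta2 and Krt8 lie lower in both Suz12KO arrays than in both WT arrays, and Jarid2, Pou5f1, Sox2, Nanog, Tbx3, Tcl1 and Hprt lie higher.

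In all 1270 calls both arrays of a genotype lay on the same side of both arrays of the other, which was the case for 52.9% of all tested genes and for 33.3% by chance. The calls rest on a variance model in which the spread depends on signal level. Without that dependence limma called 0 genes at an adjusted p under 0.05 (smallest 0.0999), with 2332 genes at an unadjusted p under 0.05 against 2966 with it. In simulated data that variant also recovered 0% of 4-fold changes. The simulated variances were drawn from the model with that dependence, so this cannot show which model holds for these arrays. Centring each array on its median moved the median log2 fold change of the tested genes from 0.04 to -0.13 and the calls to 294 higher and 1243 lower, so that 19.13% of calls were higher in place of 44.9%. Averaging probe sets gave 305 higher and 306 lower, and leaving out WT replicate 1 or 2 gave 408 or 391 lower. Among the genes with the largest changes, calls were lost without Suz12KO replicate 1 for Galnt6, Stag3 and Fcna, without Suz12KO replicate 2 for Galnt6, Aire, Liph and Fcna, and without WT replicate 2 for Fcna and Ltb (adjusted p 0.0508 to 0.252). Stmn4, Serpinb9, Ror2, Nog, Mroh2a, Trp53inp2 and Lrfn4 lost theirs without WT replicate 1 or WT replicate 2 (adjusted p 0.0538 to 0.279). Without Suz12KO replicate 2, Nog changed by -1.87 and Lrfn4 by -1.65, and without Suz12KO replicate 1, Ltb changed by -1.62. The remaining Suz12KO signals of Nog (95.5) and Lrfn4 (126) lay within the range of the unused spikes, so these 2 fold changes are not exact.

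Pluripotency genes were higher in Suz12KO. Of 38 measured members of this list, 30 rose, 1 fell and 7 did not pass, with a median log2 fold change of 0.80. Nanog rose by 2.04 (SE 0.08, limma adjusted p = 1.38e-06), from a signal of 1994 ± 86.9 to 8253 ± 273 (mean ± SD, n = 2). The core factors Pou5f1, which encodes Oct4, and Sox2 rose by less, 0.69 (SE 0.06) and 0.86 (SE 0.08). Tcl1 and Tbx3 rose most among members above the unused spikes in WT, the germline and pluripotency regulator Prdm14 was at least 3.18-fold higher, and Fgfbp1 fell by 0.82. Klf4 (2.03), Esrrb (1.77) and Klf2 (1.76), transcription factors of naive pluripotency, also rose and are named here after their values were seen, while Lin28a (-0.14) did not pass. There were 31 rises and 1 fall when adjusted over the list alone. The list passed the set test (camera adjusted p = 3.21e-25), but not with an estimated correlation between genes (adjusted p = 0.139). The estimate itself, -0.015, lay below the preset 0.01, so correlation between the genes does not explain that loss. Prdm14 lost its call without Suz12KO replicate 1 (adjusted p = 0.0513), and Fgfbp1 without WT replicate 1 or WT replicate 2 (adjusted p 0.118 and 0.0807).

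Hox genes, classical PRC2 targets, showed no call when represented by their brightest probe sets. Of 33 on the array, 11 had enough signal to be tested, and 0 rose or fell by limma over all genes or adjusted over the list alone. The median of the 11 was 0.18 (camera adjusted p = 0.479), and the median of all 33 lay at percentile 51.5 among random lists of matched signal. Hoxa5 (0.18) and Hoxc6 (0.11, and -0.06 after centring), the brightest, did not pass. A second, dimmer Hoxa5 probe set read 84.4 and 28.4 in WT and 293 and 295 in Suz12KO, and a second Hoxc6 probe set read 419 and 96.4 in WT and 503 and 505 in Suz12KO. With the mean of a gene's probe sets the Hoxa5 log2 fold change passed the test (1.20, limma adjusted p = 0.0432), and the median log2 fold change of Hox genes was 0.51 (camera adjusted p = 0.35). Among 39 other homeobox genes Hesx1, a forebrain and epiblast repressor, rose by 1.68 (SE 0.33) and 38 did not pass, with a list median of 0.23 (camera adjusted p = 0.479) and 1 rise adjusted over the list alone. Without Suz12KO replicate 2 the Hesx1 call was lost (adjusted p = 0.0515), and without WT replicate 1 the Hox median was -0.0047 and Hoxa5 was -0.10. The Hoxc6 log2 fold change was -0.11 without Suz12KO replicate 1 and 0.33 without Suz12KO replicate 2.

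Lineage markers moved in both directions, and none of the 4 lists passed the set test. Of 29 endoderm genes, 4 rose and 5 fell, with Rhox5, the basement membrane chain Lama1 (2.31, SE 0.22) and Apoe (0.58) higher and Krt19 (-2.15), Serpinh1 (-1.05) and Cited1 (at least 2.29-fold) lower. Among 34 neural and ectoderm genes, Otx2, a factor of epiblast and anterior brain, rose by 1.81 and 5 members fell, among them Sox11 (-2.27), Nes, which encodes the intermediate filament nestin (-1.41), and Stmn2 (-1.12). Tbx3 rose and Bmp4, a ligand of mesoderm and trophoblast induction, fell by 1.87 among 22 primitive streak and mesoderm genes, and the other 20 did not pass. Of 18 trophoblast genes, Esx1 (2.12), Rhox6 (1.59) and Tfap2c (0.72) rose, while the keratins Krt8 (-1.91, SE 0.06) and Krt18 (-1.43, SE 0.06) and Id2 (-0.83) fell. Gata4 (0.13, limma adjusted p = 0.949, and -0.03 after centring) and Gata6 (-0.05, adjusted p = 0.953), the endoderm regulators, did not pass. Gata4 read 110 and 154 in WT, within the range of the unused spikes, and 54.4 and 351 in Suz12KO, so its fold change is poorly measured. The Gata4 log2 fold change was -1.06 without Suz12KO replicate 2, where every reading lay within that range, and 1.32 without Suz12KO replicate 1. The Gata6 log2 fold change was -0.14 and 0.04 without the same arrays. A second Gata4 probe set, lower in mean log2 signal, read 43.9 and 32.3 in WT and 345 and 357 in Suz12KO. Camera adjusted p was 0.479 for endoderm, 0.222 for neural, 0.386 for mesoderm and 0.700 for trophoblast genes, whose medians were -0.05, -0.15, 0.18 and 0.04, with a mean of 0.03 for endoderm, a test pointing down for trophoblast, and a median log2 fold change of trophoblast genes of -0.0077 under quantile normalization and -0.13 after centring. When adjusted over the list alone, 5 rose and 6 fell among endoderm, 2 and 5 among neural, 1 and 1 among mesoderm and 5 and 4 among trophoblast genes. Calls were lost without WT replicate 1 for Cited1, Rhox6 and Tfap2c, without WT replicate 2 for Cited1, Esx1 (1.40) and Tfap2c, and without Suz12KO replicate 1 for Esx1, Rhox6 and Tfap2c (adjusted p 0.0529 to 0.199), and without Suz12KO replicate 2 the neural median was 0.05. Averaging probe sets ended the calls of Nes (-0.77), Id2 (-0.62) and Esx1, leaving out probe sets with an s, x or a suffix that of Id2 (-0.66, adjusted p = 0.617), testing without a filter those of Cited1, Esx1, Rhox6 and Tfap2c, and centring that of Tfap2c (0.55). The Id2 probe set without such a suffix read 191 and 161 in WT and 72.8 and 149 in Suz12KO. These lie under the highest unused spike of any array (195), so it says little about the brighter Id2 probe set.

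Markers of fibroblasts, which serve as feeder cells in some embryonic stem cell cultures, were lower in Suz12KO. Of 22 measured members, 9 fell, 1 rose and 12 did not pass, with a median of -0.76. The collagen Col1a1 went from 2729 ± 184 to 441 ± 9.01 (mean ± SD, n = 2), a log2 fold change of -2.58 (SE 0.14). Thbs1, a matricellular glycoprotein, fell by 2.34 (SE 0.09) and the smooth muscle actin Acta2 by 2.25 (SE 0.06), from a WT signal of 33799 ± 80.3. Col6a2 rose by 0.70, but its second probe set, also above the unused spikes, changed by -0.60 (533 and 554 in WT, 290 and 425 in Suz12KO). The counts adjusted over the list alone were 11 lower and 1 higher, and camera gave an adjusted p of 1.65e-08 (adjusted p = 0.206 with an estimated correlation). The Acta2 probe set is of a kind that can detect related transcripts: averaging probe sets gave -1.08, and those without such a suffix gave -0.54 (adjusted p = 0.729). The Acta2 probe sets without such a suffix lay under the highest unused spike of any array (195). Both of these values therefore say little about the fall of the bright one. Col6a2 lost its call without WT replicate 1, WT replicate 2 or Suz12KO replicate 2 (adjusted p 0.0676 to 0.210), under centring (0.53), averaging (0.05), a pseudocount of 1, no filter and robust estimation.

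Some cell cycle inhibitors fell and some cell division genes rose, and the groups were not tested against each other. Of 15 inhibitors and arrest genes, 6 fell, 0 rose and 9 did not pass (median -0.35), including the CDK inhibitor Cdkn2b (-1.03), Gadd45b (-0.97) and the p53 target Phlda3 (-0.82), and Cdkn2a (0.03, limma adjusted p = 0.977, and -0.03 under quantile normalization and -0.14 after centring) did not pass. Of 36 cell division genes, 7 rose, 0 fell and 29 did not pass (median 0.22), including the mitotic cyclin Ccnb2 (0.60, SE 0.09), the replication licensing factor Cdt1 (0.49) and Mcm6 of the replicative helicase (0.43). With p-values adjusted over the list alone, 7 inhibitors fell, and 16 division genes rose and 1 fell. Camera adjusted p was 0.0061 and 8.13e-06, and with an estimated correlation the adjusted p was 0.354 and 0.206. Centring brought the division median to 0.05 and ended the call of Mcm6 (0.26), averaging probe sets ended those of Cdt1, Mcm6 (0.18), Gadd45b (-0.31) and Phlda3, and testing without a filter that of Phlda3. Cdkn2b lost its call without WT replicate 1 (adjusted p = 0.101) and Phlda3 without WT replicate 1 or WT replicate 2 (adjusted p 0.0682 and 0.0546). Phlda3 was -0.44 and the Cdkn2a log2 fold change -0.41 without Suz12KO replicate 1, and Cdkn2a was 0.46 and the inhibitor median -0.19 without Suz12KO replicate 2.

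Some germline genes rose and some imprinted genes fell. Of 19 measured germline and meiosis genes, 5 rose, 0 fell and 14 did not pass, and the median was 0.96, against 0.62 for all 30 on the array without a filter on dim genes. Tex19.1, expressed in germ cells and pluripotent cells, rose by 2.04 (SE 0.10), from 1162 ± 37.2 to 4816 ± 173 (mean ± SD, n = 2), beside the meiotic cohesin Stag3 and Stra8, a meiotic entry factor (1.17). Of 32 imprinted genes, 9 fell, 0 rose and 23 did not pass (median -0.23), among them Rian (-0.9997), Meg3 (-0.66) and Gnas (-0.92). The imprinted list held 43 genes, of which 39 had a probe set with 1 symbol. Any member read only by probe sets with several symbols is not in these counts. There were 5 rises among germline genes, and 13 falls and 1 rise among imprinted genes, when adjusted over the list alone. Camera adjusted p was 1.64e-05 for germline and 0.0019 for imprinted genes, and with an estimated correlation the adjusted p was 0.206 and 0.394. Among probe sets without an s, x or a suffix the median log2 fold change of imprinted genes was -0.013 (camera adjusted p = 0.0429). Averaging probe sets took it to -0.030, ended the list's call (camera adjusted p = 0.0586) and those of Gnas (-0.03), Meg3 (-0.50) and Stra8, and without such suffixes Gnas read 0.26. The Gnas probe set used in the main test read 14288 and 13124 in WT, and every other one read 325 or less in each array. Both Gnas values therefore say little about the fall of the bright probe set. Stra8 lost its call without WT replicate 2, Suz12KO replicate 1 or Suz12KO replicate 2 (adjusted p 0.0969 to 0.173), after centring (adjusted p = 0.0603) and without a filter, the imprinted median was -0.13 without WT replicate 1, and Stag3 without Suz12KO replicate 1 (adjusted p = 0.0849).

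Ribosomal protein genes were slightly higher in Suz12KO. Of 24 measured, 8 rose, 0 fell and 16 did not pass, with a median of 0.18, and Rps14 (0.35, SE 0.05), Rpl4 (0.33) and Rps15 (0.27) rose most among those 8. When adjusted over the list alone 15 rose, and camera gave an adjusted p of 1.65e-08 (adjusted p = 0.355 with an estimated correlation). Centring took the median to 0.0090 and ended the list's call and those of all 3 genes, and quantile normalization ended the list's call and that of Rps15 (0.16).

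Signalling and chromatin genes changed singly. Among 38 ligands and antagonists 3 rose and 3 fell: Fgf4, the main FGF ligand of embryonic stem cells, rose by 1.81 (SE 0.15), Gdf3 by 0.73 and the Nodal antagonist Lefty2 by 0.67, and Nog, Bmp4 and Wnt4 (-1.12) fell. Of 31 other chromatin regulators 3 rose and 2 fell: Dnmt3l, a cofactor of de novo DNA methylation, went from 3861 ± 49.2 to 10412 ± 433 (mean ± SD, n = 2), a log2 fold change of 1.43 (SE 0.07), Kdm5b rose by 0.50 and Hdac1 by 0.28, and the H3K27 demethylase Kdm6b (-1.06) and the acetyltransferase Ep300 (-0.70) fell. Of 18 PRC1 subunits L3mbtl2 rose by 0.73 and Yaf2 (-0.94) and Phc2 (-0.84) fell. The counts adjusted over the list alone were 3 higher and 3 lower among ligands, 5 and 3 among chromatin regulators and 2 and 3 among PRC1 subunits. Camera adjusted p was 0.700 for ligands (median 0.11, mean -0.07, and a median of -0.05 after centring), 0.479 for chromatin regulators (median 0.05, and -0.12 after centring) and 0.530 for PRC1 (median 0.22). Calls were lost without WT replicate 1 for Lefty2, Wnt4, Kdm5b, Hdac1 and Kdm6b, without WT replicate 2 for Lefty2, Hdac1, Ep300 and Yaf2, without Suz12KO replicate 1 for Hdac1, Kdm6b (-0.70) and Ep300, and without Suz12KO replicate 2 for Lefty2 and Hdac1 (adjusted p 0.0521 to 0.237), and the chromatin median was -0.05 without Suz12KO replicate 2. Centring ended the calls of Lefty2 (0.50), Kdm5b (0.33) and Hdac1 (0.11), averaging probe sets those of Lefty2, Kdm5b, Hdac1, Kdm6b and Ep300, testing without a filter those of Lefty2, Hdac1 and Ep300, and leaving out probe sets with an s, x or a suffix those of Kdm6b (-0.02) and Phc2 (-0.70).

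The lists for interferon, metabolism, sex, totipotency and housekeeping did not shift as sets. Of 13 interferon and antigen presentation genes, Oas1a, Ifitm1 (1.18, SE 0.07) and Ifitm2 (0.85) rose and B2m, the light chain of class I histocompatibility molecules, fell by 1.07. Of 23 glycolysis and hypoxia genes 3 rose and 2 fell, including the phosphofructokinase Pfkp (1.32, SE 0.13), Aldoa (0.25), Egln1 and the glucose transporter Slc2a1 (-0.29). Among 12 housekeeping genes Hprt, Rps18 (0.20) and Pgk1 (0.17) rose and Tuba1a (-1.28), B2m and Ywhaz (-0.25) fell, with the calls of Rps18 (0.03) and Pgk1 (0.0069) lost under centring and under quantile normalization (Pgk1 -0.0092). The Y-linked Eif2s3y (0.19, limma adjusted p = 0.615) and Xist, the RNA of X inactivation (0.46, adjusted p = 0.197), did not pass, nor did Usp17la (0.55) and Zfp352 (0.11, and -0.06 after centring) of the 2-cell-stage list. The Usp17la log2 fold change was 0.29 without Suz12KO replicate 2. The Zfp352 log2 fold change was 0.20 without WT replicate 1 and 0.02 without WT replicate 2. Medians were -0.0051 for interferon (mean 0.18, median 0.0097 under quantile normalization, and median 0.56 with camera adjusted p = 0.00028 among probe sets without an s, x or a suffix), 0.14 for glycolysis (-0.03 after centring), -0.15 for housekeeping (mean 0.20, and camera adjusted p = 0.0445 under quantile normalization), 0.21 for the 3 measured Y genes and Xist (0.021 without WT replicate 1, 0.53 without WT replicate 2 and 0.45 without Suz12KO replicate 2), and 0.11 for the 3 measured 2-cell-stage genes (-0.05 under quantile normalization and -0.06 after centring). The main camera adjusted p was 0.479, 0.386, 0.673, 0.479 and 0.700 in that order, and adjusted over the list alone 3 rose and 2 fell, 5 and 3, 4 and 5, 0 and 0, and 0 and 0. Calls were lost without WT replicate 1 for Pgk1, Slc2a1, Rps18 and Ywhaz, without WT replicate 2 for these and Aldoa, without Suz12KO replicate 1 for Aldoa, Pgk1 and Ywhaz and without Suz12KO replicate 2 for Aldoa and Rps18 (adjusted p 0.0535 to 0.184). The interferon median was 0.0093 without WT replicate 1, 0.01 without Suz12KO replicate 1 and 0.08 without Suz12KO replicate 2, centring ended the call of Aldoa (0.08), and testing without a filter ended those of Aldoa, Pgk1, Rps18 and Ywhaz, averaging probe sets those of Aldoa, Pgk1 and Rps18, and leaving out probe sets with such suffixes those of Pgk1 and Rps18.

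**Figure D2:**
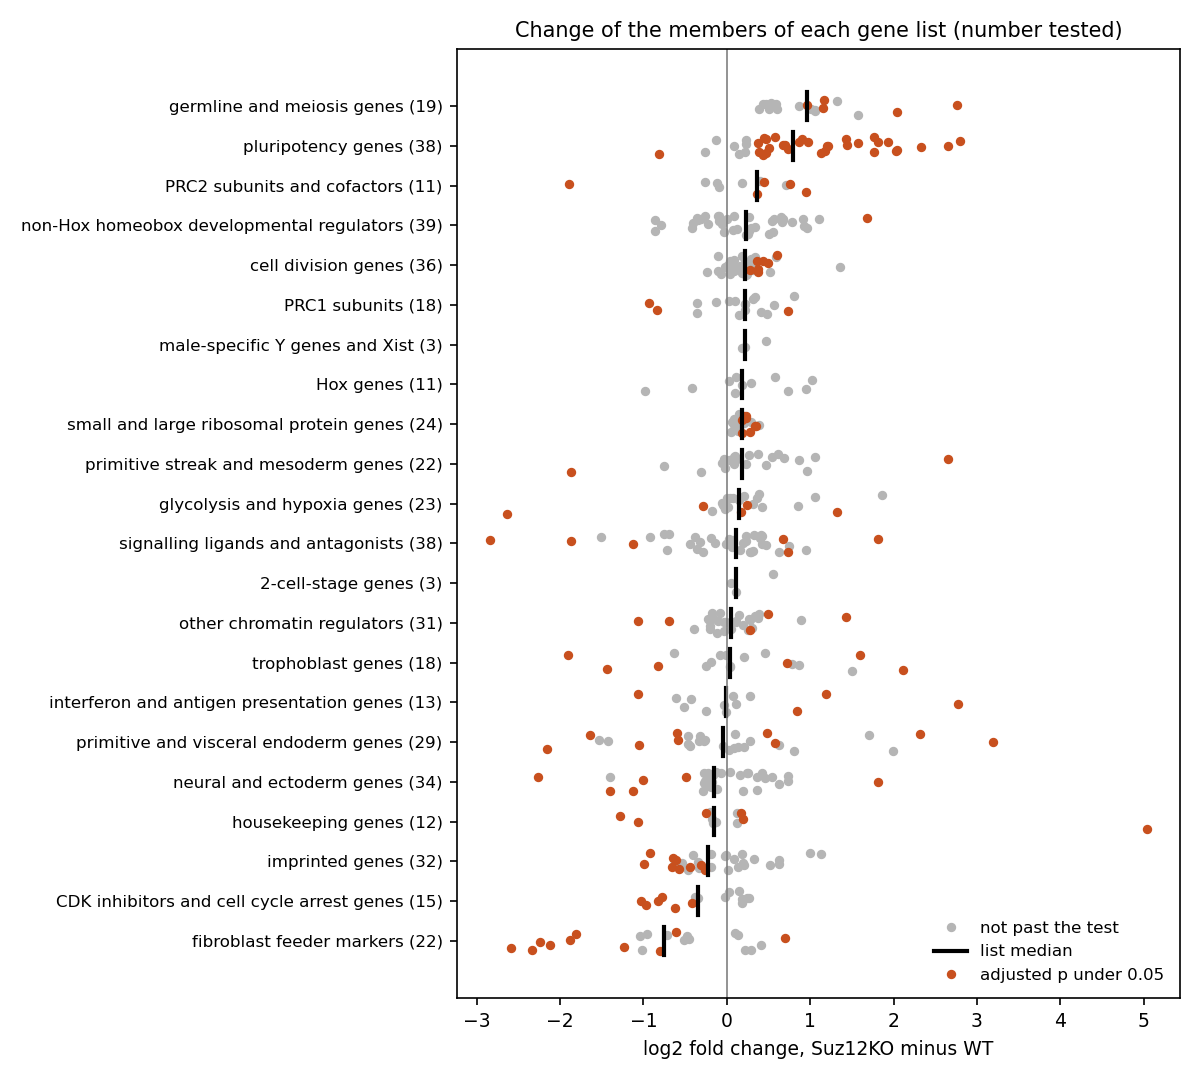
Log2 fold change, Suz12KO minus WT, of each tested member of the 22 gene lists, with the number tested in parentheses, members past the test at an adjusted p under 0.05 in orange, the others in grey and the list median as a black bar. Germline (0.96) and pluripotency genes (0.80) have the highest medians and fibroblast feeder markers the lowest (-0.76), and centring each array on its median, which lowers all genes by the same amount, turns the medians of the trophoblast, signalling, chromatin, glycolysis and 2-cell-stage lists below 0.

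Genes on the X chromosome were higher in Suz12KO more often than autosomal genes. Of 416 X-linked genes 45 rose (10.8%), against 521 of 12252 autosomal genes (4.25%), an odds ratio of 2.73 (Fisher's exact test, two-sided p = 3.65e-08, across genes, which are not independent replicates, and chosen after seeing the data). Hprt, Rhox5, Pnma5, Esx1 and Rhox6 were among those that rose. The shares that fell, 7.21% and 5.46%, were not distinguishable by Fisher's exact test (two-sided p = 0.126). The median log2 fold change of X-linked genes was 0.13, at percentile 99.99 among random gene sets of the same size, and medians outside the central 95% were also found for chromosome 7 (0.07, percentile 98.9), chromosome 8 (-0.0036, percentile 1.97) and chromosome 18 (-0.03, percentile 0.54). With quantile normalization or a filter at the 50th percentile of signal, 2 chromosomes lay outside in place of 4, and centring would shift all chromosomes alike.

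**Figure D3:**
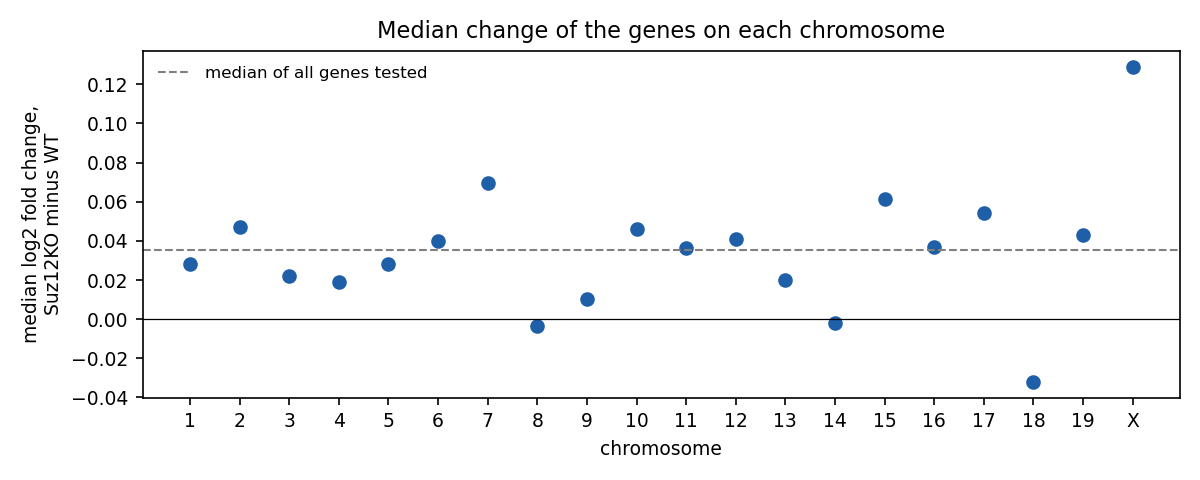
Median log2 fold change, Suz12KO minus WT, of the tested genes on each autosome and the X chromosome (points), with the median of all tested genes (0.04) as a dashed line. The X chromosome has the highest median (0.13) and chromosome 18 the lowest (-0.03).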

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

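The test on these probe sets was chosen after the data had been seen. Probe sets without a single gene name were outside the comparisons above, and some of them changed. Of 3576 such probe sets above the signal filter, 98 were higher and 42 lower in Suz12KO by limma with Benjamini-Hochberg adjustment. They stood out as signal in data that no comparison used. A probe set with several symbols rose by 2.74 (SE 0.17), and another with several symbols fell by 2.76 (SE 0.19). No explanation was tested for these.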

How the results depend on the processing

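No alternative was chosen after the results were seen. Signal near the unused spikes limits fold changes of dim genes, and each fit without an array assumes that the lone array varies like the other genotype. Where a value below changed, the cause was not tested.

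Centring on array medians gave 294 genes higher and 1243 lower (354 lower at least 2-fold), and the mean of a gene's probe sets 305 and 306 (137 lower at least 2-fold). Without trend, eBayes called 0 higher and 0 lower (0 and 0 at least 2-fold), with 2332 genes at an unadjusted p under 0.05. Leaving out 1 array gave 391 to 740 lower (391 without WT replicate 2, 408 without WT replicate 1). With an estimated inter-gene correlation, an option with fewer degrees of freedom, 0 gene lists passed. Outside the central range lay 2 chromosome medians with quantile normalization and 2 with the mean at or above the 50th percentile. The replicate numbers did not pair the arrays (differences between replicates correlated at 0.0154 between genotypes, across genes), and a replicate block gave 1016 higher and 1082 lower (268 higher at least 2-fold), and the median log2 fold change of PRC2 subunits and cofactors passed with it (camera adjusted p = 0.0368). The Suz12 level was -1.67 by the mean of its probe sets and -1.89 with eBayes without trend (limma adjusted p 0.0602 and 0.123, over a range from 1.16e-09 with a replicate block), past the test in all other settings.

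Of 90 other named genes past the test, 3 reversed in any setting: Eed with the mean of probe sets (-0.42), Gnas without s, x or a suffixes (0.26) and Pgk1 with quantile normalization (-0.0092). Of those not past it, Rbbp4 passed with centring (-0.28) and Hoxa5 with the mean of probe sets (1.20), and these reversed: Ezh1 (-1.07) and Rbbp4 (0.19) without suffixes, Phf19 (-0.12) and Gata6 (0.25) with the mean of probe sets, Zfp352 (-0.050), Gata4 (-0.020) and the Cdkn2a log2 fold change (-0.028) with quantile normalization, and the Hoxc6 log2 fold change (-0.060), Zfp352 (-0.057), Gata4 (-0.033) and Cdkn2a (-0.14) with centring. The second Eed probe set, and those of Ezh1 without suffixes, lay under the highest unused spike of any array (195). The Gnas probe sets without suffixes read 325 or less in each array, against 14288 and 13124 in WT for the one used in the main test. Leaving out 1 array gave a Phf19 log2 fold change of 0.090 to 0.72, a Rbbp7 log2 fold change of -0.14 to -0.043, a Usp17la log2 fold change of 0.29 to 0.82 and a Zfp352 log2 fold change of 0.017 to 0.20. It moved Phf1 from -0.59 to 0.054, Hoxa5 from -0.10 to 0.46, Hoxc6 from -0.11 to 0.33, Gata4 from -1.06 to 1.32, Gata6 from -0.14 to 0.042 and Cdkn2a from -0.41 to 0.46. The WT signal of Gata4 lay within the range of the unused spikes, so its fold changes are poorly measured.

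List medians that reversed were, with centring, the median log2 fold change of trophoblast genes (-0.13) and those of signalling (-0.055), chromatin (-0.12), glycolysis (-0.027) and 2-cell-stage genes (-0.057). With quantile normalization they were trophoblast (-0.0077), interferon (0.0097) and 2-cell-stage genes (-0.050), and with no filter endoderm (0.087), trophoblast (-0.0045) and interferon (0.022). With a filter at the 50th percentile interferon was 0.036, with the mean of probe sets PRC2 -0.12, chromatin -0.037 and interferon 0.082, and without suffixes chromatin -0.018, Y genes and Xist -0.018 and interferon 0.56. Leaving out 1 array gave medians of -0.0047 to 0.51 for Hox, -0.22 to 0.050 for neural, -0.073 to 0.083 for interferon genes and -0.053 to 0.092 for the median log2 fold change of other chromatin regulators. The 7 lists past the test kept their direction in all settings.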

Other observations

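Actin cytoskeleton genes were lower in Suz12KO. In a list of 33 measured genes, written after the falls of Acta2 and Acta1 had been seen, 23 fell and 0 rose (median -0.89). Cald1, which encodes the actin-binding protein caldesmon, fell by 1.65 (SE 0.10), the intermediate filament gene Vim by 1.45 (SE 0.06), Csrp1 by 1.44 and Vcl, which encodes the focal adhesion protein vinculin, by 1.06. Targets of ERK signalling, in a list written after the values of Dusp4 (-2.15), Dusp6 (-0.86) and Spry4 (0.26) had been seen and without these, moved down more often than up. Of 24 measured, 10 fell, among them Rhob (-1.55), Dusp14 (-1.49) and Phlda1 (-1.22), and Etv5 (0.47) and Tfap2c rose. Members that did not pass include Fos (-0.46), Egr1 (-0.05), Spry2 (-0.01), Spry1 (0.28) and Etv4 (0.61). Of 18 genes of the post-implantation epiblast, the stage after naive pluripotency, 6 fell, including Cdh2, which encodes N-cadherin (-1.87), and Sox4 (-1.36), and 0 rose, but of the 9 members not already seen when the list was written only 2 fell. Cdh2 was among the members already seen. These 3 lists and all tests below except those on actin genes and on second probe sets were chosen after the results they measure had been seen at least in part, and 5 explanations were tried for the first pattern, 3 for the second and 2 for the third.

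The first pattern is the rise of pluripotency genes in Suz12KO. Other cells diluting stem cell RNA in WT and lacking these transcripts would lower all members by a common fold, if probe sets respond alike to RNA amount. Of 38 members, 29 had a 95% interval that left out the list's median, but these intervals measure spread between arrays only. The quartiles of the members were 0.40 and 1.54. This argues against dilution as the whole cause only if probe sets do respond alike, which was not tested. A part stays open because fibroblast markers (median -0.76) were higher in WT. Centring the arrays left the median at 0.63, which argues against array scaling, and the X minus autosome median of 0.098 (95% bootstrap interval 0.045 to 0.153) argues against 2 active X chromosomes. Weaker ERK signalling (median of its targets -0.36, camera p = 1.33e-05) and a shift away from the post-implantation epiblast (-0.39, p = 1.31e-05) both remain candidate explanations, but with an estimated correlation both adjusted p were 0.0518, and Otx2 (1.81) and Hesx1 (1.68), epiblast factors not in that list, rose. Both epiblast p-values used all 18 members, of which only 9 had not been seen when the list was written. They therefore rest in part on the values that prompted the list and are no independent test of that shift. Without members already seen, the medians were -0.46 for 23 ERK targets (10 fell and 1 rose) and -0.42 for 9 epiblast genes (2 fell and 0 rose). Genotype, clone and parental line cannot be separated in this design.

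The second pattern is the fall of fibroblast feeder markers, for which the labels name no feeder layer or sort and of which 2 are also in another list. A first test for feeder fibroblasts in WT, on a common fold, decides nothing: 20 of 22 members had a 95% interval that left out the fold of Col1a1, but Col1a1 was the most changed member, and a common fold need not hold for genes that stem cells also express or that lie near background. A second test was chosen after that outcome: of 6 abundant matrix genes, Col1a1, Col1a2 and Col3a1 were above the unused spikes in both WT arrays (Col1a1 at 2729) and Dcn, Lum and Postn were not, so 3 of 6, and feeders as a source of the list's signal cannot be told apart from expression in the stem cells. Lower actin cytoskeleton gene expression in Suz12KO is a candidate explanation for part of the list (-0.89, the median of 33 actin genes not in the fixed lists, camera p = 2.41e-26, adjusted p = 0.0485 with an estimated correlation). Fibroblasts express these actin genes too, so feeders in WT would give the same fall, and this test does not separate these explanations.

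The third pattern is Hprt, with a signal of 263 and 141 in WT and 6994 and 6746 in Suz12KO. Some embryonic stem cell lines carry a deletion in Hprt, so a hypothesis is that the WT cells come from such a line and the Suz12KO cells do not. The higher WT signal was 3.83% of the Suz12KO mean, but the housekeeping genes Tuba1a and B2m moved by -1.28 and -1.07, against the condition set for that test, and Hprt has 1 probe set used here, so the explanation cannot be told apart from an effect of genotype. Sequence differences under single probe sets as a general source of large changes are argued against by 185 changed genes with a second probe set, whose ratio of log2 fold changes had a median of 0.726, with 168 in the same direction, but this does not test Hprt itself.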
